A study of Caenorhabditis elegans with 4 samples.

How the data were processed

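Peak lists from TBP-1 ChIP-seq of mixed-stage N2 embryos were analysed. Per the labels' protocols, live embryos were fixed in 2% formaldehyde for 30 minutes, quenched with 125 mM glycine and sonicated, 2 mg of extract went into each immunoprecipitation, and 10% was set aside as input. Libraries were made with single-end adaptors that carry an index. The aligner BWA, with no version, and the genome build ce10 are named per the submitters' processing notes. Per the file headers, peak positions are on WormBase WS220, and the source column of each list names MACS for the 2 replicate lists and MACS v2 for the series list. The caller's settings, the control library, any duplicate or multi-mapping filter and the way the series list was made are not given in the sources used here. MACS builds peaks from read pile-ups against a control, so read depth, fragment length and the control library all affect how many peaks are called and how wide they are.

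Each deposited list gives a start, an end and 1 score per peak, as deposited by the authors. The scale of the score is not stated. No replicate score lies below 50, and scores were compared only as ranks within a list. The lists give no read counts, fold enrichment, summit or q-value, so the depth is unknown and no interval on binding strength can be given. The 95% Wilson intervals printed beside shares cover the counting of peaks only. No peak list of an input library was analysed here, so background in the input could not be set beside the ChIP values.

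Samples were grouped by their titles into TBP-1 ChIP (2 replicates) and input (2 replicates). The labels do not say whether the replicates came from separate cultures, so the spread between them may be technical. The series list was treated as a pooled list of the TBP-1 ChIP samples, with no SD or n. This is an assumption, since the way it was made is not given. Peaks on the mitochondrial chromosome were left out of all comparisons. A chromosome's length was taken as the end of its last peak in any list, since a table of WS220 lengths was not used here. A gene table of another build, WBcel235, was at hand and was not used for positions, so peaks were not assigned to genes. The planned comparisons of promoters, gene lists and TATA boxes, which needed an annotation or genome of the build of the files, were therefore not run, and the rule for named items was applied to peak positions alone.

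The comparisons, their alternatives and the rule for named peaks were fixed before the data were examined. Splits by score other than the stronger 50%, windows of 500 kb, broad peaks over 3 kb, chromosome ends, and the comparisons within the autosomes and for single chromosomes' centres were added after seeing the data. The rule took the 15 strongest series-list peaks found in both replicates and the 5 strongest peaks of each replicate not found in the other, with ties broken by chromosome and start. Peaks were called shared when they overlapped by at least 1 bp. Chance overlap came from 1000 circular shifts of one list along its own chromosomes, which keep peak widths and spacing, with a one-sided permutation p. The alternative that asked for an overlap of 50% of the shorter peak used fewer shifts, with a smallest possible permutation p of 0.0050. Spearman's rho used 100000 permutations, with each shared replicate 2 peak paired with the strongest replicate 1 peak that overlapped it. Shares of peaks per chromosome were tested against shares of length with two-sided exact binomial tests. Autosome centres were the middle 50% of each autosome, and a peak was placed by its centre. P values were adjusted by the Benjamini-Hochberg method within each family of tests, with a threshold of 0.05. The alternatives were other overlap definitions, stronger or equally long lists, merged neighbours, random positions, covered base pairs, the middle 33.3% of the autosomes and each replicate left out.

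The tests were checked on simulated lists. With 600 of the 1684 replicate 1 peaks planted in a simulated list, 633 overlaps were found, a number that includes chance overlaps. Unrelated lists gave a p under the threshold in 1% of the draws. For the X share of replicate 1, uniform positions were called in 4.5% of the draws. X at 1.3 times the rate of the autosomes, which is less than 1.3 times its length share, was called in 97%. These X calls used p values without adjustment. Both simulations placed peaks independently of each other, as the binomial test itself assumes. These rates therefore hold for independent peaks only, and the rate of false calls for clustered peaks was not simulated. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.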

Results

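Chromatin bound by TBP-1 was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in wild-type Caenorhabditis elegans embryos. TBP-1 is the worm TATA-binding protein, a general transcription factor that is used at promoters of all nuclear RNA polymerases. The strain was N2, the standard laboratory wild type, and the embryos were of mixed stages and, per the labels, of both sexes (males and hermaphrodites), at 20 °C. The series held 4 samples, of which 2 were immunoprecipitated with a rabbit polyclonal antibody against TBP-1 and 2 were input DNA. Peak lists were analysed for the 2 ChIP replicates and, as another list, for the whole series. The labels do not say whether the replicates came from separate cultures, so their spread may be technical. Replicate 1 had 1685 peaks, replicate 2 had 2660 and the series list had 4214. The read depth behind these lists is unknown, and the input libraries were not analysed here as samples of their own.

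Peak shape differed between the lists. Replicate 1 peaks had a median width of 511 bp and covered 1.12% of the nuclear genome. Replicate 2 peaks were wider, with a median of 844.5 bp, and covered 2.71%. Series-list peaks were the narrowest, with a median of 271 bp, and covered 1.58%. The authors' scores ran from 50.2 to 3230.05 in replicate 1, from 50.04 to 3211.42 in replicate 2 and from 1.36 to 246.25 in the series list. Their scale is not stated in the files, so they were used only to rank peaks within a list. Ranks were tied near the top, since 60 peaks of replicate 1 and 175 of replicate 2 had the score 3100.

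The first question was whether the replicates located TBP-1 at the same places. Most replicate 1 peaks were also replicate 2 peaks: 1435 of 1684 nuclear peaks (85.2%, 95% Wilson interval 83.4 to 86.8) overlapped a replicate 2 peak by at least 1 bp. In the other direction, 1319 of 2660 replicate 2 peaks (49.6%, 47.7 to 51.5) overlapped a replicate 1 peak. The longer list thus added 1341 peaks of its own, and the shorter list 249. Circular shifts of one list along its chromosomes gave mean overlaps of 4.46% and 2.72%, with maxima of 7.24% and 4.74% over 1000 draws. Both observed overlaps lay above every draw (one-sided permutation test, adjusted p = 0.0010, the smallest the draws can give).

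The strongest peaks of each list were mostly present in the other, and the weakest were found less often. This split by score was chosen after seeing the data. In the strongest 10% of the replicate 2 list, 266 of 266 peaks overlapped a replicate 1 peak, and in the weakest 10% 17 of 266 did (6.39%, 4.03 to 10.0). Replicate 1 peaks went from 55.4% (47.8 to 62.7) in the weakest 10% to 98.2% (94.9 to 99.4) in the strongest. Unshared replicate 2 peaks had a median score of 87.81, against 777 for shared ones. Unshared replicate 1 peaks had a median score of 80.39, against 346.93. Across the 1319 shared replicate 2 peaks, the ranks of the scores in the 2 libraries were related (Spearman's rho = 0.87, permutation p = 1.0e-05, the smallest the draws can give). Without pairs in which either score reached 3100, rho was 0.80 over 1121 pairs. This relation is across peaks of 2 libraries, and peaks are not independent replicates.

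**Figure D1:**
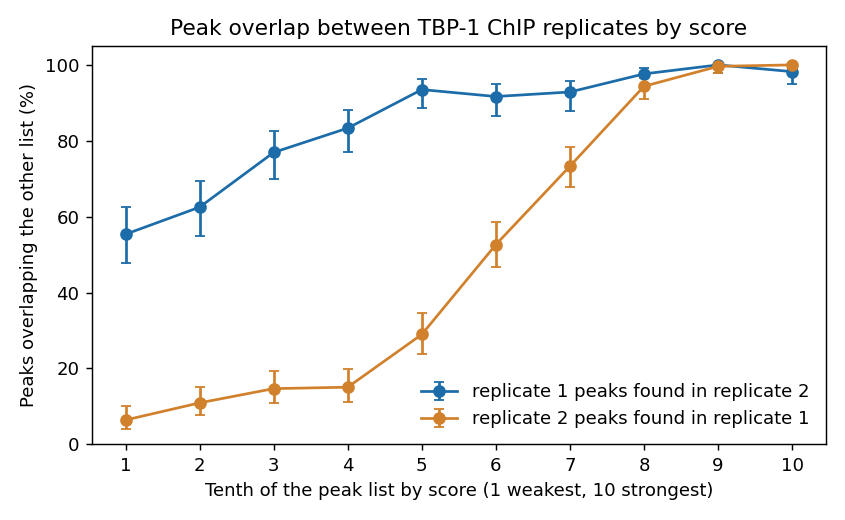
Share of peaks (%, y axis) that overlapped a peak of the other replicate by at least 1 bp, for lists ranked by the authors' score and cut into 10 equal parts (x axis, 1 weakest to 10 strongest). Points are shares and bars are 95% Wilson intervals. Replicate 2 peaks rise from 6.39% in the weakest part to 100% in the strongest, and replicate 1 peaks from 55.4% to 98.2%.

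The 15 strongest series-list peaks that were found in both replicates all ranked above the 90th score percentile in each replicate. On X there were 8 of them, on I, IV and V 2 each, on II 1 and on III 0. All positions are on the WormBase WS220 build. The highest series-list score, 246.25, was shared by chromosome I 13463658 to 13464273, IV 143625 to 144217, V 19642850 to 19643825, and X 1880658 to 1881138, 9637029 to 9638199, 13045896 to 13046748 and 13120902 to 13121633. The last of these X peaks also had the second highest score of replicate 1, 3205.71, and the score 3100 in replicate 2. The next peaks were chromosome II 13834287 to 13835019, IV 5966818 to 5967430, and X 352868 to 353591 and 12889573 to 12890724, each with a score of 246.22. The remaining 4 were X 489488 to 490232 with a score of 245.17, I 8223770 to 8224791 and V 9503233 to 9503798 with 244.44 each, and X 14115348 to 14115898 with 244.26. These peaks were 481 to 1171 bp wide. No gene, exon or promoter was assigned to any peak, because a gene annotation of WS220 was not used here.

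All of the 5 strongest replicate 1 peaks without a replicate 2 counterpart were over 3 kb wide, and 1 of the 5 strongest replicate 2 peaks without a replicate 1 counterpart was. The strongest was chromosome I 15060216 to 15071361, 11146 bp wide with a score of 3100, near the right end of the chromosome. Chromosome I is known to carry the tandem array of large ribosomal RNA genes at that end, but the array was not located here. The others were III 1017280 to 1020692 (score 2733.24), X 4025945 to 4029270 (2569.14), X 14384930 to 14389748 (1100.69) and IV 8575051 to 8578123 (877.05). The 5 strongest replicate 2 peaks without a replicate 1 counterpart were III 349229 to 350586 (score 1193.39), X 4222183 to 4223602 (970.39), III 424485 to 426497 (925.14), II 9631637 to 9633224 (900.33) and V 2302098 to 2305557 (810.53). All 10 of these peaks were also in the series list.

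The second comparison placed the list of the whole series against the replicates. Of its 4203 nuclear peaks, 1448 (34.5%, 33.0 to 35.9) overlapped peaks of both replicates, 1317 (31.3%) only of replicate 2 and 219 (5.21%) only of replicate 1. The remaining 1219 (29.0%, 27.7 to 30.4) overlapped neither. The share found in at least 1 replicate was 71.0%. It was 65.8% when replicate 1 was left out and 39.7% when replicate 2 was left out. Peaks found in both replicates had a median score of 73.22 and a median width of 436.5 bp. Peaks found in neither had a median score of 5.59 and a median width of 181 bp. Of the 1051 strongest series-list peaks, 1026 were in both replicates and 1 was in neither, a split by strength chosen after seeing the data. Conversely, 95.3% (94.2 to 96.2) of replicate 1 peaks and 93.7% (92.7 to 94.5) of replicate 2 peaks overlapped a series-list peak. The overlaps of the series list with each replicate, in both directions, exceeded every one of 1000 circular shifts (one-sided permutation test, adjusted p = 0.0010). So did the share found in at least 1 replicate when both replicate lists were shifted (mean 5.44%, one-sided permutation p = 0.0010). The share in neither is its complement. The shares found in both or in 1 replicate only were not tested against shifts. How the series list was made is not stated, and as a list of the same series its overlap with the replicates is not independent evidence for a peak.

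The third comparison asked how TBP-1 peaks were distributed over the chromosomes. In C. elegans hermaphrodites both X chromosomes are subject to dosage compensation, which lowers their transcription. Males have a single X, and the labels give both sexes for these embryos, but the share of males was not examined. X held more TBP-1 peaks than its length predicts in every list. X makes up 17.7% of the nuclear length and held 377 of 1684 replicate 1 peaks (22.4%, 20.5 to 24.4), 627 of 2660 replicate 2 peaks (23.6%) and 942 of 4203 series-list peaks (22.4%, 21.2 to 23.7). The mean of the 2 replicates was 22.98% ± 0.84 (SD, n = 2), over lists that share part of their peaks. Relative to length, X held 1.27 times the expected number in replicate 1 (1.16 to 1.38), 1.33 times in replicate 2 (1.24 to 1.43) and 1.27 times in the series list. Each excess passed the two-sided exact binomial test, with adjusted p = 3.0e-06, 1.5e-13 and 9.7e-14 (Benjamini-Hochberg over 18 tests, 6 chromosomes in 3 lists). X had the highest density of the 6 chromosomes in each list, at 21.3, 35.4 and 53.2 peaks per Mb in that order. The binomial test treats peaks as independent, and the chromosomes themselves are 6 units, among which a first rank has a probability of 0.17.

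Among the autosomes, chromosome V had the fewest peaks for its length and chromosome III the most. V held 0.85 times the expected number in replicate 1, 0.74 times in replicate 2 and 0.78 times in the series list (exact binomial test, adjusted p = 0.0025, 3.9e-12 and 7.5e-13). III makes up 13.7% of the length and held 15.3%, 15.2% and 15.5% of the peaks, an excess that passed the exact binomial test in the series list (adjusted p = 0.0033) and missed the threshold in replicate 1 (0.11) and replicate 2 (0.067). In a comparison within the autosomes, chosen after seeing the data, III was above its length share in all 3 lists, with ratios of 1.18, 1.19 and 1.19 (exact binomial test, adjusted p = 0.012, 0.00084 and 6.5e-06). In that comparison V had ratios of 0.90, 0.80 and 0.83, and the replicate 1 value did not pass the threshold (exact binomial test, adjusted p = 0.057, 3.1e-07 and 1.8e-07). Chromosome I passed it there in replicate 2 and the series list, with ratios of 1.12 and 1.13 (exact binomial test, adjusted p = 0.029 and 0.0022), and not in replicate 1, with a ratio of 0.997 (adjusted p = 1 in the exact binomial test). Over all 6 chromosomes, II was below its length share by the exact binomial test in replicate 2 (0.89 times, adjusted p = 0.028) and in the series list (0.88 times, adjusted p = 0.0025), and its replicate 1 ratio of 0.89 missed the threshold (adjusted p = 0.10). Chromosomes I and IV did not pass that test in any list.

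**Figure D2:**
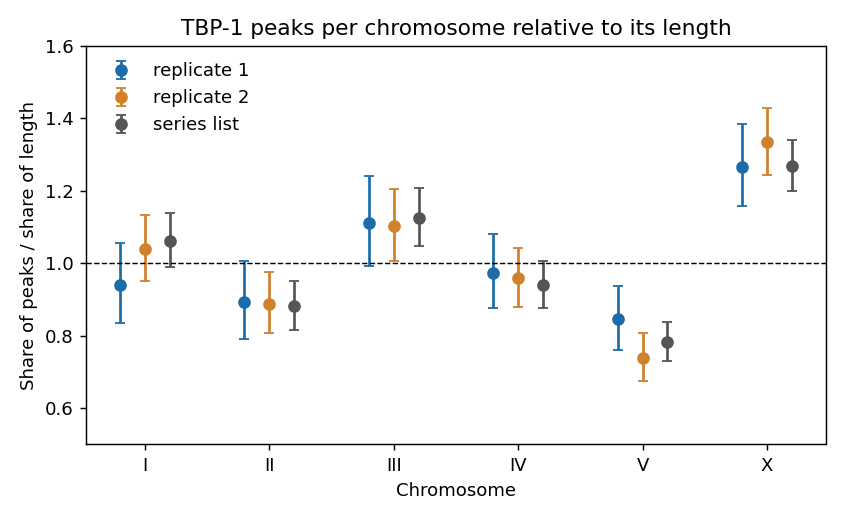
Share of TBP-1 peaks on each chromosome divided by that chromosome's share of the nuclear length (y axis, not starting at 0), for the 2 replicates and the series list (x axis, chromosomes). Points are ratios, bars are 95% Wilson intervals and the dashed line marks a ratio of 1. X lies between 1.27 and 1.33 in the 3 lists and V between 0.74 and 0.85.

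The last comparison set chromosome centres against arms, since worm autosomes carry gene-rich centres and repeat-rich arms. The middle 50% of the autosomes held 50.5% of replicate 1 autosomal peaks (660 of 1307, 47.8 to 53.2), 52.5% of replicate 2 peaks (1068 of 2033, 50.4 to 54.7) and 52.0% of series-list peaks (1695 of 3261, 50.3 to 53.7). The excess passed the test in replicate 2 and the series list (exact binomial test, two-sided, adjusted p = 0.037 for both) and not in replicate 1 (adjusted p = 0.74). By chromosome, a split chosen after seeing the data, V had 56.6%, 57.8% and 57.2% of its peaks in its middle 50% (exact binomial test, adjusted p = 0.12, 0.011 and 0.0016), and I to IV had 46.2% to 53.1% over the 3 lists, with none past the threshold. Neither pooled call held when only the stronger 50% of each list was used, with shares of 50.05% and 50.8%.

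**Figure D3:**
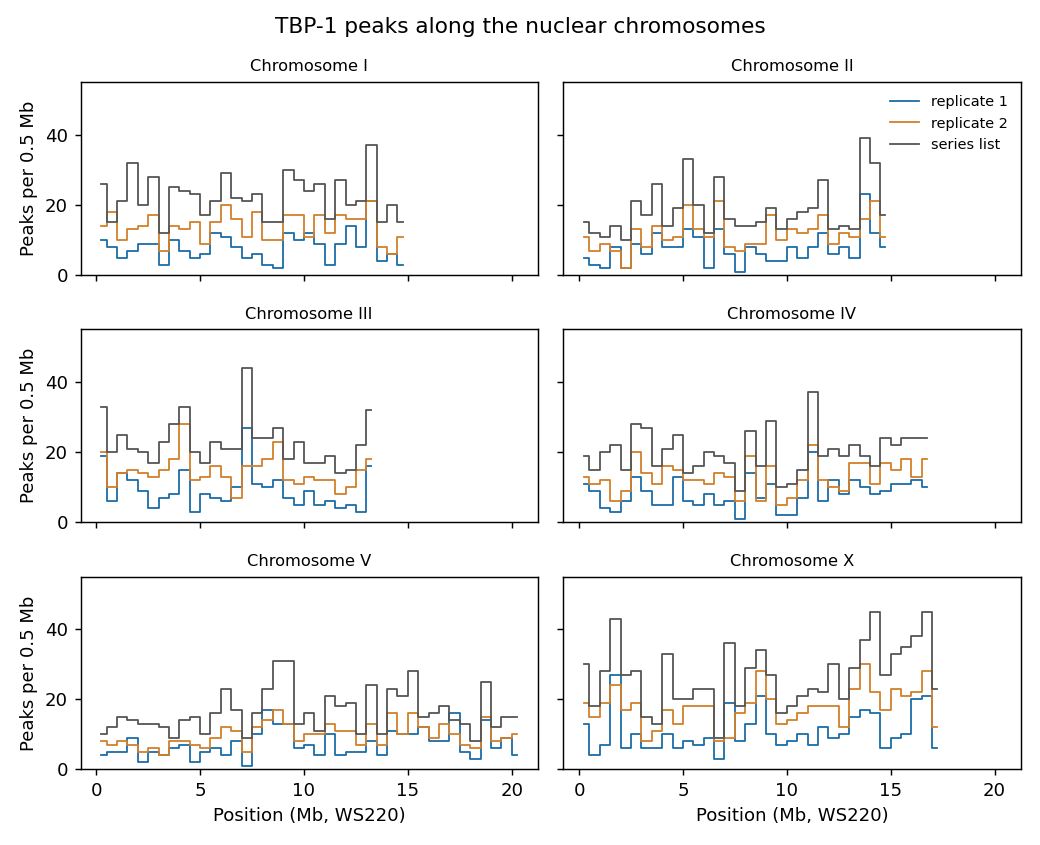
Number of TBP-1 peaks per window of 0.5 Mb (y axis) along each nuclear chromosome (x axis, Mb on WS220) in the 2 replicates and the series list, 1 line per list. The fullest windows of the series list are X 14 to 14.5 Mb and X 16.5 to 17 Mb with 45 peaks each, and III 7 to 7.5 Mb with 44.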

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

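One result was picked out by the planned rules, a signal outside the comparisons of the report. The series list held 11 peaks on the mitochondrial chromosome, above the bound of 3 that the rule sets for a count of 0, with scores of 3.71 to 36.03. They covered 63.4% of that chromosome up to its last peak, against 1.58% of the nuclear chromosomes. Replicate 1 had 1 mitochondrial peak, from 10675 to 13010 with a score of 317.93, and replicate 2 had 0. The bound treats peaks as independent counts, which neighbouring peaks on 1 chromosome are not. The series list also names another caller version, so its count is not comparable with those of the replicates. No sample group had enough members for the search for outlying samples.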

How the results depend on the processing

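The overlap between replicates, the rank relation, the overlap with the series list and the X excess kept their direction in all alternatives run (14, 3, 6 and 18). They also kept their side of the threshold wherever an alternative had a p value. The mean X share with either replicate left out had none, and with 2 replicates it could not move from the mean by more than their SD. Equally long lists leave the replicate 1 list as it was, so that setting is no separate check of its X share. Replicate 1 peaks found in replicate 2 ranged from 62.6% (centres within 100 bp) to 94.2% (stronger peaks of each list), replicate 2 peaks in replicate 1 from 39.6% to 71.8% (equally long lists), and the X share from 21.9% to 26.1%. With either replicate left out, the mean X share was 22.4% to 23.6%, the mean centre share 50.5% to 52.5% and the series list's overlap 39.7% to 65.8%. The autosome centre share was not stable. For replicate 1 it turned below 50% when peaks closer than 500 bp were merged (49.5%). For replicate 2 the call was lost with the stronger peaks (50.05%), equally long lists (51.1%), merged peaks (52.3%) and the middle 33.3% of the length (34.3%). For the series list it was lost with the stronger peaks (50.8%), merged peaks (51.8%) and the middle 33.3% (33.9%), and turned with the same number of strongest peaks (49.96%). The settings with fewer peaks also have less power, and the cause was not tested further. Leaving out peaks over 3 kb and using only peaks found in both replicates were chosen after seeing the data. No other strength column existed for the rank relation. Promoter, gene list and TATA box alternatives were not run, nor was the gene-based X share. No paired analysis was possible because no values of the input libraries were analysed here. Unknown read depth limits what the missing weak peaks of either replicate show.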

Other observations

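Merging of neighbouring peaks and the stronger 50% of each list were planned before the data were examined (the bound for the latter was set after its result was seen), the windows were added after the X excess was seen with a bound set before their own result, and the other tests in this part were chosen after the results were seen. The middle 50% of X held 46.9% of its replicate 1 peaks, 46.4% of its replicate 2 peaks and 43.4% of its series-list peaks. The difference from the autosomes, among which V had the most peaks in its middle 50%, was -3.55, -6.12 and -8.56 percentage points, and passed Fisher's exact test in replicate 2 and the series list (adjusted p = 0.012 and 1.1e-05) but not in replicate 1 (0.24). Against 50% of its own length, X passed in the series list only (exact binomial test, adjusted p = 0.58, 0.28 and 0.0011). The fullest series-list windows of X lay to the right of that middle. Its left and right outer parts were not compared with each other. Among the strongest 10% of peaks, X held 57 of 169 in replicate 1 (33.7%), 74 of 266 in replicate 2 (27.8%) and 119 of 421 in the series list (28.3%). Against the X share of the weaker peaks (21.1%, 23.1% and 21.8%), this was higher in replicate 1 and the series list (Fisher's exact test, adjusted p = 0.0013 and 0.0046) and did not pass in replicate 2 (0.094). Over all peaks the calls differed: the mean score percentile on X and on the autosomes was 54.4 and 48.8 in replicate 1, 52.3 and 49.3 in replicate 2, and 51.4 and 49.6 in the series list (permutation test, adjusted p = 0.0021, 0.029 and 0.088). Higher strength on X thus passed both tests in replicate 1 only. The Fisher, binomial and permutation tests above count peaks as independent units, which neighbouring peaks on 1 chromosome are not. Their p values may therefore be too small.

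Many broad peaks were found in both libraries. Of 35 replicate 1 peaks over 3 kb, 24 overlapped one of the 46 peaks over 3 kb of replicate 2. The widest lay on chromosome V from 17119878 to 17132354 in replicate 1 (12477 bp) and from 17119662 to 17132760 in replicate 2 (13099 bp), both with a score of 3100. The right part of V is known to carry the array of 5S ribosomal RNA and SL1 RNA genes, but its position was not examined. On chromosome I, the region from 15060206 to 15071384 was the widest peak of the series list (11179 bp) and had no peak in replicate 2. Of all replicate 1 peaks, 11 of 35 broad (31.4%) and 238 of 1649 narrower ones (14.4%) were missing from replicate 2, and of all replicate 2 peaks, 3 of 46 broad (6.52%) and 1338 of 2614 narrower ones (51.2%) were missing from replicate 1 (Fisher's exact test, adjusted p = 0.013 and 5.5e-10). In the stronger 50% of replicate 1, 10 of 34 peaks over 3 kb were missing from replicate 2, against 23 of 808 narrower peaks (Fisher's exact test, adjusted p = 2.8e-07). In the stronger 50% of replicate 2 the relation was the other way, with 1 of 42 broad and 212 of 1288 narrower peaks missing from replicate 1 (Fisher's exact test, adjusted p = 0.012).

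The first pattern weighed is the X excess, 199 series-list peaks above the number expected from length. Weak peaks near the caller's threshold do not account for it, since X still held 22.9% of the stronger peaks of the series list. Splitting of broad regions into pieces closer than 500 bp does not either, since X held 21.9% after such peaks were merged. Pieces further apart stayed unmerged. X also held 22.7% of the base pairs covered by the series list, a share that does not count pieces. With windows of 500 kb as the unit, X had 26.7 ± 8.94 peaks per window (SD, 35 windows) and the autosomes 19.7 ± 6.65 (162 windows). The two-sided permutation p was 2.0e-05, the smallest the draws can give, so clusters within single windows alone do not explain the excess. The windows are not replicates of X, and permuting them cannot exclude clusters that span several windows. In the series list every X window from 14 to 17 Mb held 27 to 45 peaks, above the X mean. The other X windows held 9 to 43. From 14 to 17 Mb the X windows held 6 to 21 peaks in replicate 1 and 17 to 28 in replicate 2. How much of the excess lies there was not examined. With windows as the unit, replicate 1 gave 10.7 peaks on X against 7.94 on the autosomes (permutation p = 0.0027). Uneven read background between chromosomes, which the input reads would show, and a higher number of TBP-1 targets on X, such as tRNA genes, remain open, and no biological explanation was tested.

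The second pattern is the 1219 series-list peaks found in neither replicate list. Of these, 7.38% lay in the stronger 50% of the list, against 95.1% of the peaks found in both. Whether they were too weak for the threshold in 1 library stays open, since their low scores had prompted that explanation and the share restates them. Whether deeper pooled reads, a looser threshold or the other caller version brought them in was not tested. Their X share was 19.9% (17.8 to 22.3), against 23.7% (21.6 to 25.9) for peaks found in both, 24.3% (22.1 to 26.7) for those in replicate 2 only and 16.4% (12.1 to 21.9) for those in replicate 1 only, and these shares were not tested against each other.

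The third pattern is a peak at the left end of all 6 nuclear chromosomes, starting at base 1 or 2, in each of the 3 lists. Circular shifts put a peak in the first 2 kb of 0.17 to 0.45 chromosomes on average and of at most 3 (permutation p = 0.0010 in each list, the smallest the draws can give). Chance position as the shifts model it therefore does not account for the pattern. The pattern and the 2 kb bound were picked after seeing these data, and the 3 lists are not independent, so the p values are not separate tests. Weak calls made at a chromosome's edge cannot be told apart from real enrichment, since the median score percentile of the 6 peaks, 53.7 in replicate 1 and 57.5 in replicate 2, met the bound of 50 that would argue against weak calls by less than the peaks' spread (44.8 to 75.5 and 30.5 to 73.4). In the series list the median was 71.6, further above the bound, with a spread of 12.5 to 80.9 that also reaches below it. The peaks of III and IV were the weakest in each list. Their percentiles were 44.8 and 49.5 in replicate 1, 30.5 and 30.9 in replicate 2, and 12.5 and 20.4 in the series list. Those of I, II, V and X were 51.1 or more in all 3 lists. Letting the spread decide was settled after these values were seen, and on the bound alone weak calls would have been argued against. Reads from telomere repeats mapped to the ends were not tested. At the right ends, 3 of 6 chromosomes in replicate 1, 1 of 6 in replicate 2 and 6 of 6 in the series list had a peak within 2 kb. Each right end was set by the last peak in any list, so at least 1 list reaches it by construction. That the series list reached all 6 was not fixed by this, and the true chromosome ends were not used here.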
